A study of Solanum lycopersicum with 9 samples.

How the data were processed

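Leaf RNA of the tomato cultivar Diana (Solanum lycopersicum) was sequenced after treatment with 0 (control), 15 or 30 mM p-hydroxybenzoic acid (PHBA), a phenolic acid. Plants were about a month old when treated and were sampled 2 days later, per the labels' protocols. Each dose had 3 libraries, 9 in all, numbered 1 to 3 in the labels. The labels also say that equal parts of RNA of the same treatment were mixed, and no label says that the 3 libraries of a dose came from separate plants. The p-values therefore measure only the spread between these libraries, which may be technical. RNA was extracted with Trizol and treated with DNase I, per the labels' protocols.

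The authors deposited FPKM values (fragments scaled by the length of the sequence and by the mapped fragments of the library) with 2 decimals for 82125 sequences in the 9 libraries. The sequence names carry the name of the Trinity assembler and of 1 of the 9 libraries, per the file headers and the values, so each sequence came from an assembly of 1 library. The submitters' processing notes name Trimmomatic 0.36, FastQC 0.11.5, RSEM and DESeq, with no role stated. The assembler's version, how the 9 assemblies were merged, the mapper and any filter are not given in the sources used here. A second deposited file gives, per the file headers, protein domain and pathway descriptions (Pfam, InterPro, KEGG and others) with no measured values. It has 15048 lines for 14831 sequences, of which 14720 are in the FPKM table. The annotation gives no tomato gene names or positions, and none of the sequence names matched the reference gene table, so sequences are named by their identifiers with the family the annotation gives. Several sequences may be fragments or near-identical copies of 1 gene whose reads were split, so counts of sequences are not counts of genes.

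Values were used as deposited, and no value column was left unused. Sequences with at least 0.5 FPKM in at least 3 of the 9 libraries were kept (44203); 13634 of these are annotated and 30569 are not. The latter are called sequences outside the annotation. They stand in for the long non-coding RNAs the series is about, because the files mark no sequence as non-coding, and they may include unannotated pieces of coding transcripts. FPKM are not counts, so no count model was used. With limma 3.58.1 (R 4.3.3 and version 1.17.8 of its package data.table), log2(FPKM + 1) was fitted for the 3 groups in 1 model over all 9 libraries, which leaves 6 residual degrees of freedom, followed by empirical Bayes moderation with a mean trend. The 3 two-sided contrasts were 15 mM against control, 30 mM against control and 30 mM against 15 mM. P-values were adjusted with the Benjamini-Hochberg method over all sequences kept, and sequences were called at an adjusted p under 0.05. Fold changes are on the log2(FPKM + 1) scale with their standard error (SE), which understates the change of sequences with low values. Means are given with the SD of 3 libraries.

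Read counts per library are not used here. In FPKM the value of 1 read depends on the length of the sequence and on depth. Relative depth was therefore read from sequences above 0 in at most 4 libraries, as the most frequent ratio between a library's values and those of control replicate 1, among values of at least 0.3 FPKM in both. It was 0.88 to 1.22. No counting interval can be given for single values.

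Gene lists were fixed before the data were examined, as words to be matched in the annotation, and so were the model, the filter, the rule for named sequences and most alternatives. The 32 lists were light reactions, carbon fixation, chlorophyll breakdown and senescence, antioxidant enzymes, glutathione S-transferases, UDP-glycosyltransferases, cytochrome P450, ABC and MATE transporters, phenylpropanoid and lignin enzymes, flavonoid enzymes, class III peroxidases and laccases, pathogenesis-related proteins, wound-response proteins, the jasmonate, ethylene, abscisic acid, auxin and salicylate pathways, heat shock proteins, dehydrins and LEA proteins, WRKY, MYB and NAC factors, cell wall loosening and pectin, ribosomal proteins, histones and cyclins, nutrient transporters, sugar and starch, immune receptors, and markers of glandular trichomes, of xylem and root, and of pollen and flower. The last 3 were meant to stand for other cell types or organs that a leaf sample could hold. A sequence may be in several lists, so counts of different lists are not independent. For each list the called members were counted, also with p adjusted over the list alone, and limma's camera compared the list with the other annotated sequences at a preset correlation of 0.01, adjusted over 96 tests (32 lists in 3 contrasts). The background of this test was first all 44203 sequences and was narrowed to the 13634 annotated ones, which are the sequences a list could hold, after the first result had been seen. As a further test chosen after the data were seen, 348 Pfam families with at least 10 kept members were tested the same way.

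The named sequences are the 10 called with the largest rise and the 10 with the largest fall per contrast, with a mean of at least 5 FPKM in the higher group, no overlap between the values of the groups compared and a named function; up to 4 called members of each list with the smallest p (the 2 with the highest mean where none was called); and the 3 largest rises and falls outside the annotation with a mean of at least 1 FPKM. Only part of them is printed.

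The steps were tested on simulated data, with 200 of 44203 sequences of the 30 mM against control comparison changed in each of 5 simulated sets. The changed sequences were drawn from those with a mean log2(FPKM + 1) of at least 1, which is about 1 FPKM. Where a fall would have come near 0, a rise was used. Recovery at lower values was not tested, and 22446 of the sequences kept had a mean under 1 FPKM. The model recovered 37.6% of sequences with a log2 change of 1, 81.8% with 2 and 91.5% with 3, and 63 of 765 calls (8.2%) were false. Alternatives were other pseudocounts, filters and scalings, a fit of 6 libraries, a replicate block, library weights, robust moderation, a minimum fold change, leaving out each library and a camera test with an estimated correlation. FPKM summed per gene was left out because the files give no gene for each sequence. Plots were drawn with matplotlib 3.10.9 (Python 3.11.15).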

Results

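Leaf transcripts of the tomato cultivar Diana were measured 2 days after treatment with 0, 15 or 30 mM p-hydroxybenzoic acid (PHBA), a phenolic allelochemical, that is, a compound by which plants can inhibit the growth of other plants. Each dose had 3 libraries, and the 9 libraries share a table of FPKM values for 82125 de novo assembled sequences, of which 44203 were abundant enough to be tested. Of these, 13634 had a protein annotation and 30569 had none. Summed FPKM was 349076 to 366748 in the control libraries, 353902 to 364475 at 15 mM and 366432 to 383347 at 30 mM. Relative depth was 0.96 to 1.22 in the controls, 0.98 to 1.14 at 15 mM and 0.88 to 1.16 at 30 mM, against 1 in control replicate 1. The 4 most abundant sequences, all without annotation, held 39.4 to 45% of the FPKM in the controls, 26.9 to 44.6% at 15 mM and 33.5 to 42.4% at 30 mM. The first principal component held 28.3% of the variance and placed the controls at -60.7 to -44.5, the 15 mM libraries at -9.4, -34.3 and 0.4 (replicates 1 to 3) and the 30 mM libraries at 59 to 87. Spearman correlations across sequences were 0.643 to 0.701 within groups and 0.569 to 0.654 between groups.

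The first question was which transcripts responded to the lower dose. At 15 mM PHBA, 18 annotated sequences rose against the control, among them 3 of 40 WRKY factors, a family of DNA-binding proteins active in defence and stress responses. The WRKY sequence T15_2_TRINITY_DN9367_c0_g1 rose from 2.57 ± 0.614 to 11.4 ± 1.9 FPKM (SD, n = 3 each; log2 fold change 1.79, SE 0.18, adjusted p = 0.0249), and the WRKY sequence TCK_3_TRINITY_DN960_c0_g1 rose from 4.73 ± 0.83 to 14.9 ± 3.33 FPKM (adjusted p = 0.0322). TCK_2_TRINITY_DN946_c0_g1, which is annotated as isopenicillin N synthase-like, rose from 6.32 ± 1.07 to 24.1 ± 5.1 FPKM (adjusted p = 0.0249). T30_1_TRINITY_DN3378_c0_g1, of the FAE1 family of enzymes that elongate very long-chain fatty acids, rose from 3.65 ± 0.105 to 10.7 ± 1.5 FPKM (log2 fold change 1.32, SE 0.14, adjusted p = 0.0249). The NB-ARC sequence T30_2_TRINITY_DN299_c0_g1, with the nucleotide-binding domain of plant immune receptors, rose from 3.1 ± 0.486 to 8.32 ± 0.746 FPKM (adjusted p = 0.0249). In each of these 5 sequences all 3 treated libraries lay above all 3 controls. The groups did not overlap in any sequence called at this dose, nor in 17.1% of all sequences tested. In the whole comparison limma called 44 sequences, 37 higher and 7 lower, and 4603 had an unadjusted p under 0.05. Among annotated sequences none was called lower, with 2064 under the unadjusted threshold in both directions. The count was 793 with array weights, 213 among sequences with a mean of at least 5 FPKM, 102 with a pseudocount of 0.1 and 5 with 5, 14 in a fit of the 6 libraries alone and 4 without a filter. The split was 54 higher to 22 lower after quantile normalization and 49 to 22 after median-of-ratios rescaling. The count rested on single libraries, with 6, 5 and 11 calls without control replicate 1, 2 or 3. There were 9, 135 and 6 without 15 mM replicate 1, 2 or 3, and 11 without 30 mM replicate 1. The named calls were lost without control replicate 1 or 2 or 15 mM replicate 1 or 3 (adjusted p = 0.0923 to 0.108 for the first, 0.0967 to 0.128 for the isopenicillin N synthase-like sequence). The last was also lost without control replicate 3 (adjusted p = 0.0697). The FAE1 and NB-ARC calls were lost without any control, 15 mM replicate 1 or 3, or 30 mM replicate 1 (adjusted p = 0.0519 to 0.16; the NB-ARC call also with median-of-ratios rescaling, adjusted p = 0.0681). That of TCK_3_TRINITY_DN960_c0_g1 was lost without any library except 15 mM replicate 2 (adjusted p = 0.0534 to 0.179).

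Of the gene lists, 4 ranked above the other annotated sequences at 15 mM, although few of their members were called. The WRKY list had a median log2 fold change of 0.47 against 0.191 for all annotated sequences, with 21 of 40 members higher and none lower when adjusted over the list alone, where 25 members had an unadjusted p under 0.05. It stood above the other annotated sequences (camera adjusted p = 3.1e-10; adjusted p = 0.9944 with an estimated correlation). The NAC factors, plant transcription factors of growth, senescence and stress, had a median of 0.37, with 0 of 39 called over all sequences, 16 under an unadjusted p of 0.05 and 11 higher adjusted over the list alone (camera adjusted p = 8.8e-05; adjusted p = 0.9996 with an estimated correlation). Immune receptors had a median of 0.3, 1 of 72 called higher over all sequences and 12 adjusted over the list alone (camera adjusted p = 0.00615; adjusted p = 0.9996 with an estimated correlation; adjusted p = 0.0897 without 15 mM replicate 2). The abscisic acid list, of which 52 of 58 members are type 2C protein phosphatases, had a median of 0.27, with 7 members higher adjusted over the list alone (camera adjusted p = 0.0361; adjusted p = 0.9996 with an estimated correlation). That call was lost after quantile normalization (adjusted p = 0.0715), without control replicate 2 (adjusted p = 0.0622) and without 15 mM replicate 3 (adjusted p = 0.0551).

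Photosynthetic light reactions ranked lower than other annotated sequences at 15 mM (camera adjusted p = 9.0e-09; adjusted p = 0.9996 with an estimated correlation). None of the 83 members was called by limma, over all sequences or over the list alone, 8 higher and 2 lower members had an unadjusted p under 0.05, and the median was -0.06. The pathogenesis-related list (camera adjusted p = 0.0214, median 0.1, mean 0.09), the glandular trichome markers (adjusted p = 0.0218, median -0.03) and the pollen and flower markers (adjusted p = 0.0176, median 0.07, mean 0.12) also ranked lower, and the estimated correlation gave an adjusted p = 0.9996 (0.9944 for the trichome markers). In the first and the last of these the median and mean were above 0 while camera's direction was down. All 3 calls were lost against all sequences as background (adjusted p = 0.55, 0.157 and 0.234), after quantile normalization (adjusted p = 0.27) and without 15 mM replicate 3 (adjusted p = 0.591, 0.374 and 0.206). The trichome call was also lost without control replicate 2 (adjusted p = 0.0644) and the pollen call without control replicate 1 (adjusted p = 0.139) or 2 (adjusted p = 0.0808). Of the other 24 lists, UDP-glycosyltransferases had the most members called when adjusted over the list alone (17 higher and 3 lower of 77). None of them was called over all sequences. Cytochrome P450 (8 and 2 of 115) and cell wall and pectin sequences (8 and 2 of 81) followed. Camera called none of these 24 lists against the other annotated sequences at this dose. Against all sequences, the background used first, it called 6 of them higher: glutathione S-transferases (adjusted p = 0.00137), salicylate (0.00375), dehydrins and LEA proteins (0.00616), ethylene (0.0131), ribosomal proteins (0.0347) and sugar and starch (0.0437). The estimated correlation, run against annotated sequences, gave each of these an adjusted p = 0.9996.

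The higher dose was compared with the control to ask how far the leaf transcriptome moves under strong PHBA exposure. Among annotated sequences with a named function, a mean of at least 5 FPKM and no overlap between the groups, the largest rises at 30 mM were in an aldo/keto reductase, an alcohol dehydrogenase and a WRKY factor. The aldo/keto reductase T15_3_TRINITY_DN17633_c0_g2, of a family that reduces carbonyl compounds, rose from 0.397 ± 0.115 to 90.6 ± 46.5 FPKM (log2 fold change 5.90, SE 0.38, adjusted p = 1.3e-04). The zinc-binding alcohol dehydrogenase TCK_2_TRINITY_DN1334_c0_g2 rose from 2.19 ± 0.623 to 178 ± 63.3 FPKM (log2 fold change 5.76, SE 0.49), and the WRKY sequence T15_1_TRINITY_DN8139_c0_g1 from 0.353 ± 0.136 to 74.7 ± 25.7 FPKM (log2 fold change 5.75, SE 0.38). The alternative oxidase T15_1_TRINITY_DN706_c0_g2, a mitochondrial terminal oxidase that bypasses the cytochrome pathway, rose from 0.523 ± 0.162 to 33 ± 13.7 FPKM (log2 fold change 4.39, SE 0.40, adjusted p = 4.5e-04). The RING-type sequence T15_2_TRINITY_DN44840_c0_g1, with the in-between-RING domain of ubiquitin ligases, rose from 0.837 ± 0.279 to 70.9 ± 24.6 FPKM (log2 fold change 5.23, SE 0.35). The largest falls included T30_1_TRINITY_DN15030_c0_g1, annotated as Thi4, the enzyme that makes the thiazole part of thiamine, which dropped from 287 ± 44.1 to 52.3 ± 18.5 FPKM (log2 fold change -2.48, SE 0.32, adjusted p = 0.00191). T15_3_TRINITY_DN2708_c0_g1, of the carotenoid oxygenase family, dropped from 81.5 ± 11.9 to 18.3 ± 7.76 FPKM (log2 fold change -2.16, SE 0.26), and the helix-loop-helix factor T30_2_TRINITY_DN25782_c0_g1 from 7.97 ± 2.22 to 1.08 ± 0.485 FPKM (log2 fold change -2.10, SE 0.21). Each of these had no overlap between the 3 treated and 3 control libraries, which was a condition of their choice and not a separate result.

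In this comparison limma called 5200 of 44203 sequences, 4425 higher and 775 lower, and 2028 and 344 of them with an absolute log2 fold change of at least 1. At an unadjusted p under 0.05 there were 11526. Of the called sequences, 5197 had no overlap between the groups, as had 31.9% of all sequences tested, where chance gives 10%. Annotated sequences were called more often (24% of 13634, 2876 higher and 402 lower) than those outside the annotation (6.29%). The share of higher calls depends on the scale. It was 85.1% with FPKM as deposited, 75.5% (4552 higher, 1481 lower) with the 4 most abundant sequences left out, 54.6% (2800 and 2326) after median-of-ratios rescaling and 50.8% (2486 and 2410) after quantile normalization. The median log2 fold change of all sequences was 0.18, and of annotated sequences 0.30, as deposited. After quantile normalization these medians were -0.01 and 0.04, and after median-of-ratios rescaling -0.01 and 0.05. The list medians below are therefore to be read against 0.30, and a median is not printed for every list. The count was 2350, 2473 and 3159 without control replicate 1, 2 or 3 and 2872 without 30 mM replicate 1.

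**Figure D1:**
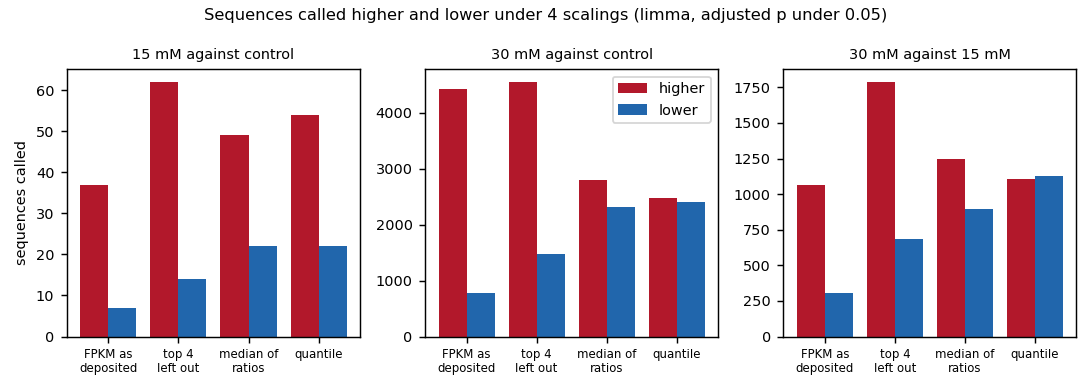
Bars give the number of sequences called higher or lower by limma (adjusted p under 0.05) in each comparison, with FPKM as deposited and after 3 rescalings. At 30 mM against control, 4425 sequences were higher and 775 lower as deposited, against 2486 and 2410 after quantile normalization, and at 30 mM against 15 mM the split moved from 1066 higher and 305 lower to 1107 and 1129.

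Photosynthesis transcripts were lower at 30 mM. Of 83 light-reaction sequences 31 fell, 10 rose and 42 did not pass (42 fell and 11 rose adjusted over the list alone), with a median log2 fold change of -0.56. Sequences with the chlorophyll a-b binding domain, the antenna proteins of the light-harvesting complexes, made up most of the falls: 19 of 24 fell, none rose and the median was -1.34. Of 20 photosystem subunits 8 fell and none rose (15 fell after quantile normalization, 19 after median-of-ratios rescaling and 17 with the 4 most abundant sequences left out). The antenna sequence T30_2_TRINITY_DN134_c0_g1 fell from 68 ± 11.3 to 19.7 ± 5.32 FPKM (log2 fold change -1.76, SE 0.20, adjusted p = 0.00109), and T30_1_TRINITY_DN11578_c0_g1 from 73.4 ± 13.9 to 27.6 ± 0.792 FPKM (log2 fold change -1.36, SE 0.17, adjusted p = 0.00146). Another antenna sequence, TCK_2_TRINITY_DN1025_c0_g2, fell from 12 ± 8.51 to 0.88 ± 0.931 FPKM (log2 fold change -2.68, SE 0.55, adjusted p = 0.0162), a call lost without control replicate 1 (adjusted p = 0.0546) or 2 (0.0514) or 30 mM replicate 1 (0.0613) or 3 (0.0519). Members that rose were 5 of 13 plastocyanin-like sequences, a copper-binding family that includes cell-surface proteins outside photosynthesis, such as TCK_2_TRINITY_DN3037_c0_g1 (3.19 ± 0.264 to 17.2 ± 2.38 FPKM), and 5 others of oxidoreductase and respiratory burst oxidase types. After quantile normalization 3 plastocyanin-like sequences rose and 2 fell. The list ranked below the other annotated sequences (camera adjusted p = 2.1e-18; adjusted p = 0.9996 with an estimated correlation). It had 43 falls and 6 rises after quantile normalization and 49 and 6 after median-of-ratios rescaling.

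Among the largest falls were 2 sequences tied to chlorophyll synthesis. T15_3_TRINITY_DN27255_c0_g1, a GUN4-like sequence of the family that stimulates magnesium chelatase, fell from 73.4 ± 9.09 to 12.9 ± 2.41 FPKM (log2 fold change -2.42, SE 0.19, adjusted p = 2.3e-04). TCK_3_TRINITY_DN2177_c0_g2, a short-chain dehydrogenase that the pathway annotation gives as protochlorophyllide reductase, fell from 9.56 ± 2.53 to 0.74 ± 0.921 FPKM (log2 fold change -2.70, SE 0.37, adjusted p = 0.00245). In the chlorophyll breakdown and senescence list 2 of 10 rose and none fell (4 and 0 adjusted over the list alone; camera adjusted p = 0.769), with 1 and 0 after quantile normalization. The stay-green sequence T15_1_TRINITY_DN12869_c0_g1, of a family that removes magnesium from chlorophyll a, rose from 3.43 ± 0.448 to 14.1 ± 2.48 FPKM (log2 fold change 1.77, SE 0.29, adjusted p = 0.00639). Of 18 carbon fixation sequences 1 rose and 1 fell (1 and 2 adjusted over the list alone), with 0 higher and 4 lower after quantile normalization and 0 and 6 after median-of-ratios rescaling. Their median was 0 and their mean -0.01, and they ranked below the other annotated sequences (camera adjusted p = 0.0255; adjusted p = 0.9996 with an estimated correlation), a call lost after quantile normalization (adjusted p = 0.0574), without 30 mM replicate 3 (adjusted p = 0.0737) and against all sequences as background (adjusted p = 0.0822).

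Transcription factors of the WRKY and NAC families rose. Of 40 WRKY sequences 27 rose and none fell (29 and 1 adjusted over the list alone), with a median of 1.27, and the list stood above the other annotated sequences (camera adjusted p = 5.7e-09; adjusted p = 0.9944 with an estimated correlation). T15_2_TRINITY_DN31591_c0_g1 rose from 0.747 ± 0.37 to 41.7 ± 6.68 FPKM (log2 fold change 4.62, SE 0.23, adjusted p = 7.7e-05) and TCK_3_TRINITY_DN6324_c0_g1 from 0.6 ± 0.13 to 20.6 ± 2.72 FPKM (log2 fold change 3.75, SE 0.20, adjusted p = 8.1e-05). Of 39 NAC sequences 23 rose and none fell (27 and 0 adjusted over the list alone), with a median of 0.75 (camera adjusted p = 9.7e-04; adjusted p = 0.9996 with an estimated correlation). TCK_2_TRINITY_DN9048_c0_g1 rose from 2.28 ± 0.772 to 81.3 ± 17.6 FPKM (log2 fold change 4.65, SE 0.36, adjusted p = 2.2e-04). After quantile normalization 21 WRKY sequences rose and 1 fell, and 14 NAC sequences rose and none fell. Of 164 MYB-type sequences 18 rose and 6 fell (23 and 7 adjusted over the list alone). Their median was 0.16 and their mean 0.15, while camera ranked them below the other annotated sequences (adjusted p = 0.0191; adjusted p = 0.9996 with an estimated correlation). After quantile normalization the split turned to 12 higher and 29 lower. Against all sequences as background the MYB list was not called (adjusted p = 0.791).

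**Figure D2:**
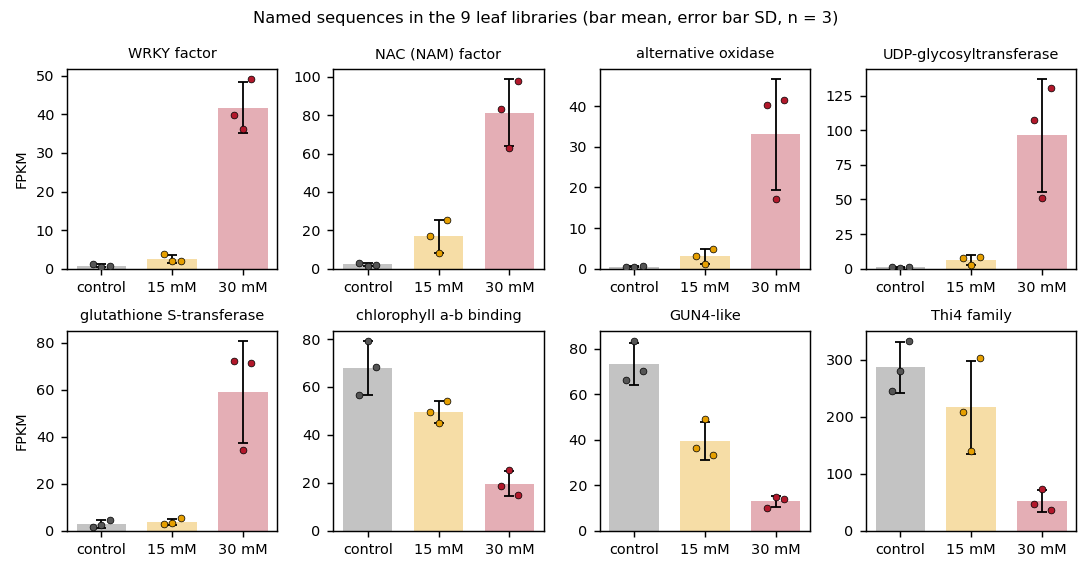
Bars give the mean FPKM of 8 named sequences in the control, 15 mM and 30 mM libraries, with the SD as error bar and each of the 3 libraries as a point. The WRKY sequence goes from 0.747 to 41.7 FPKM and the NAC sequence from 2.28 to 81.3 between control and 30 mM, while the Thi4 sequence goes from 287 to 52.3, and these directions were the same under every rescaling tried.

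Hormone-related lists shifted in part. Against all sequences, the background used first, camera called the ethylene (adjusted p = 4.6e-04), abscisic acid (7.1e-05) and salicylate (0.003) lists higher, which it did not against the other annotated sequences. The estimated correlation, run against annotated sequences, gave each an adjusted p = 0.9996. Of 84 ethylene-list sequences 28 rose and 4 fell (42 and 6 adjusted over the list alone; camera adjusted p = 0.275; 18 and 8 after quantile normalization), mostly of the AP2 domain family of ethylene-response factors, of which 19 of 57 rose and 4 fell. T30_3_TRINITY_DN32152_c0_g1 of this family rose from 0.147 ± 0.116 to 10.7 ± 1.52 FPKM (log2 fold change 3.35, SE 0.15, adjusted p = 5.0e-05). In the abscisic acid list 15 of 58 rose and none fell (18 and 0 adjusted over the list alone; camera adjusted p = 0.139), with 8 higher and 2 lower after quantile normalization and 9 and 2 after median-of-ratios rescaling. All 15 were among the 52 type 2C phosphatases, of which some members inhibit abscisic acid signalling. T30_3_TRINITY_DN975_c0_g1 rose from 1.4 ± 0.478 to 10.5 ± 0.806 FPKM. Of 32 jasmonate sequences 6 rose and none fell (7 and 0 adjusted over the list alone, camera adjusted p = 0.729). Their median was 0.14, under the 0.30 of all annotated sequences, and 3 were higher and 2 lower after quantile normalization. Among the rises was the TIFY sequence T30_3_TRINITY_DN1395_c0_g1, of the family of jasmonate repressors (4.38 ± 0.911 to 21.4 ± 5.34 FPKM). Of 9 salicylate sequences 5 rose (6 adjusted over the list alone; camera adjusted p = 0.13), including both NPR1-like sequences, relatives of the salicylate receptor. TCK_1_TRINITY_DN2979_c0_g1 rose from 3.52 ± 0.187 to 8.86 ± 1.19 FPKM. Of 37 auxin sequences 6 rose and 4 fell (6 and 4 adjusted over the list alone). Their median was -0.07 and their mean 0.05, and camera ranked them below the other annotated sequences (adjusted p = 0.00245; adjusted p = 0.9996 with an estimated correlation), with 5 higher and 11 lower after quantile normalization. The 12 GH3 sequences, enzymes that join amino acids to hormones, included 3 rises and 3 falls, such as T30_3_TRINITY_DN12909_c0_g1 (0.0467 ± 0.0289 to 7.9 ± 4.25 FPKM) and T30_3_TRINITY_DN17041_c0_g1 (25.9 ± 2.05 to 6.98 ± 2.04 FPKM).

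Lists of enzymes and transporters that act on foreign compounds moved in different ways. Among them only the glutathione S-transferases had a median above the 0.30 of all annotated sequences. Of 45 glutathione S-transferases, which join glutathione to reactive compounds, 19 rose and none fell (24 and 0 adjusted over the list alone), with a median of 0.67 (camera adjusted p = 0.00369; adjusted p = 0.9996 with an estimated correlation). T15_1_TRINITY_DN13646_c1_g1 rose from 2.89 ± 1.51 to 59.2 ± 21.6 FPKM (log2 fold change 3.94, SE 0.36, adjusted p = 4.4e-04). The camera call was lost among sequences with a mean of at least 5 FPKM (adjusted p = 0.155); after quantile normalization 18 rose and 2 fell. Of 77 UDP-glycosyltransferases, which attach sugars to small molecules including phenolics, 26 rose and 15 fell (26 and 17 adjusted over the list alone; camera adjusted p = 0.34). T30_3_TRINITY_DN5513_c0_g2 rose from 1.18 ± 0.427 to 96.2 ± 40.8 FPKM (log2 fold change 5.40, SE 0.44, adjusted p = 2.7e-04). TCK_1_TRINITY_DN1662_c0_g1 fell from 9.17 ± 2.18 to 1.22 ± 0.435 FPKM (log2 fold change -2.19, SE 0.22, adjusted p = 6.5e-04). Their median was 0.23 as deposited and -0.09 after quantile normalization. Of 115 cytochrome P450 sequences 25 rose and 12 fell (32 and 15 adjusted over the list alone). T15_1_TRINITY_DN32985_c0_g1 rose from 0.937 ± 0.233 to 37.6 ± 10.8 FPKM (log2 fold change 4.29, SE 0.25, adjusted p = 1.1e-04). The P450 median was 0.07 and the mean 0.31, while camera ranked the list lower (adjusted p = 0.0399; adjusted p = 0.9996 with an estimated correlation). That call was lost against all sequences as background (adjusted p = 0.615), after quantile normalization (adjusted p = 0.189, with 20 higher and 27 lower), and without control replicate 1 (0.0909) or 2 (0.0863), 15 mM replicate 1 (0.0571) or 30 mM replicate 1 (0.124) or 2 (0.112). Of 108 ABC and MATE transporters 28 rose and 5 fell (36 and 7 adjusted over the list alone, camera adjusted p = 0.843). Their median was 0.28 as deposited and 0 after quantile normalization, with 21 higher and 12 lower after it. The ABC sequence TCK_1_TRINITY_DN4880_c0_g1 rose from 1.55 ± 0.536 to 58.8 ± 16.4 FPKM.

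Among redox and phenolic enzymes, 9 of 32 antioxidant sequences rose and 1 fell (9 and 1 adjusted over the list alone; camera adjusted p = 0.843), with 4 higher and 6 lower after quantile normalization. Of 6 glutathione peroxidases 4 rose, such as T15_2_TRINITY_DN2126_c0_g1 from 7.39 ± 1.02 to 31.4 ± 5.97 FPKM (log2 fold change 1.94, SE 0.26, adjusted p = 0.0022). Phenylalanine ammonia-lyase T15_1_TRINITY_DN2607_c0_g1, the entry enzyme of phenylpropanoid synthesis, rose from 50.6 ± 9.12 to 108 ± 20.8 FPKM (log2 fold change 1.08, SE 0.22, adjusted p = 0.0155). Its call was lost without control replicate 1 (adjusted p = 0.0623) or 3 (0.0588), without 30 mM replicate 1 (0.0514) and after median-of-ratios rescaling (0.118). It was 1 of 2 sequences of the phenylpropanoid list, both of which were higher adjusted over the list alone (camera adjusted p = 0.298). Of 8 flavonoid sequences 2 rose (2 adjusted over the list alone; camera adjusted p = 0.585), and of 5 class III peroxidase and laccase sequences 1 rose (1 adjusted over the list alone; camera adjusted p = 0.627). After quantile normalization 1 flavonoid sequence rose and none of the 5 sequences of the class III peroxidase and laccase list was called. That list was limited by its words. Of 28 sequences of the peroxidase family PF00141, tested after the data were seen, 19 rose and 1 fell as deposited. After quantile normalization 17 of them rose and 2 fell.

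Stress and defence lists held more rises than falls, as did annotated sequences as a whole (2876 higher and 402 lower of 13634). The median of all annotated sequences was 0.30. List medians were 0.46 for heat shock, 0.57 for dehydrin and LEA, 0.51 for pathogenesis-related, 0.41 for wound-response and 0.4 for immune receptor sequences. Camera called none of the 5 against the other annotated sequences. It called all 5 higher against all sequences, the background used first (adjusted p = 1.9e-04 for heat shock, 6.2e-04 for dehydrin and LEA, 0.031 for pathogenesis-related, 0.0162 for wound-response and 1.3e-05 for immune receptor sequences). The estimated correlation, run against annotated sequences, gave each of the 5 an adjusted p = 0.9996. Of 128 heat shock list sequences 34 rose and 5 fell (56 and 7 adjusted over the list alone; camera adjusted p = 0.341), with 15 higher and 11 lower after quantile normalization. The chaperone sequence T15_2_TRINITY_DN2050_c0_g1 of the Hsp90 family rose from 7.16 ± 0.775 to 34.7 ± 21.1 FPKM (log2 fold change 1.97, SE 0.34, adjusted p = 0.00732). Of 23 dehydrin and LEA sequences, proteins of dehydration, 11 rose and 1 fell (14 and 1 adjusted over the list alone; camera adjusted p = 0.103; 8 and 3 after quantile normalization). Of 61 pathogenesis-related sequences 16 rose and 1 fell (25 and 3 adjusted over the list alone; camera adjusted p = 0.729; 9 and 4 after quantile normalization), with the chitinase T30_3_TRINITY_DN5838_c0_g1 going from 0.623 ± 0.294 to 9.35 ± 3.29 FPKM (log2 fold change 2.63, SE 0.27, adjusted p = 7.6e-04). Of 41 wound-response sequences 17 rose and none fell (18 and 2 adjusted over the list alone; camera adjusted p = 0.519; 13 and 5 after quantile normalization), including 4 of 6 trypsin inhibitors, which block the digestive enzymes of herbivores. T30_1_TRINITY_DN23892_c0_g1 of this group rose from 2.02 ± 0.5 to 25.3 ± 2.79 FPKM (log2 fold change 3.13, SE 0.22, adjusted p = 1.8e-04). Of 72 immune receptor sequences 26 rose and 1 fell (34 and 3 adjusted over the list alone; camera adjusted p = 0.113; 19 and 6 after quantile normalization), and the NB-ARC sequence T30_2_TRINITY_DN299_c0_g1 reached 18.5 ± 1.84 FPKM from 3.1 ± 0.486 (log2 fold change 2.25, SE 0.14, adjusted p = 1.1e-04).

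Of 300 sequences in the ribosomal protein list 95 rose, 1 fell and 204 did not pass (159 and 2 adjusted over the list alone), with a median of 0.57, and the list stood above the other annotated sequences (camera adjusted p = 0.00901; adjusted p = 0.9996 with an estimated correlation; adjusted p = 0.0926 among sequences with a mean of at least 5 FPKM). TCK_2_TRINITY_DN839_c0_g1, a large-subunit protein, rose from 10.4 ± 1.49 to 38.7 ± 10.5 FPKM (log2 fold change 1.77, SE 0.25, adjusted p = 0.00314). After quantile normalization 37 rose and 14 fell. Of the 235 members described as ribosomal 77 rose and none fell, and of the other 65, such as Hsp90 chaperones and GHMP kinases, 18 rose and 1 fell. Of 81 cell wall and pectin sequences 18 rose and 7 fell (21 and 11 adjusted over the list alone). Camera ranked them lower (adjusted p = 0.0369; adjusted p = 0.9996 with an estimated correlation), although their median was 0.18 and their mean 0.22. That call was lost against all sequences as background (adjusted p = 0.615), after quantile normalization (adjusted p = 0.275, with 11 higher and 16 lower) and without control replicate 1 (0.0727) or 2 (0.0706) or 30 mM replicate 1 (0.085) or 3 (0.0796). T30_2_TRINITY_DN11898_c0_g1, a xyloglucan-modifying enzyme, rose from 3.23 ± 1.1 to 40.7 ± 12.1 FPKM (log2 fold change 3.28, SE 0.34, adjusted p = 7.5e-04). In contrast, 3 of 8 pectate lyases fell and none rose. Of 71 histone and cyclin sequences 15 rose and 1 fell (16 and 2 adjusted over the list alone; camera adjusted p = 0.769), with 12 higher and 8 lower after quantile normalization, and 7 of the 16 core histones rose. Of 61 nutrient transporters 13 rose and 1 fell (15 and 1 adjusted over the list alone; camera adjusted p = 0.973), with 8 and 8 after quantile normalization. The fall was in the ammonium transporter T30_1_TRINITY_DN46563_c0_g1, from 11.9 ± 1.34 to 3.02 ± 0.67 FPKM (log2 fold change -1.69, SE 0.17, adjusted p = 7.0e-04). Of the 4 sequences of the ammonium transporter family, 3 rose and only this 1 fell.

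In the sugar and starch list 27 of 134 rose and 3 fell (33 and 6 adjusted over the list alone; camera adjusted p = 0.402), but 12 were higher and 25 lower after quantile normalization. The sucrose synthase T15_3_TRINITY_DN3657_c0_g1, which splits sucrose, rose from 3.13 ± 0.335 to 26.4 ± 9.48 FPKM (log2 fold change 2.68, SE 0.28, adjusted p = 8.2e-04). Of 9 glandular trichome markers, limma called 0 over all sequences or over the list alone, and 1 had an unadjusted p under 0.05 (camera adjusted p = 0.36). Of 27 xylem and root markers 2 rose and 1 fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.219), with 0 higher and 5 lower after quantile normalization. Of 30 pollen and flower markers 6 rose and 4 fell (9 and 6 adjusted over the list alone; camera adjusted p = 0.107), with 4 higher and 7 lower after quantile normalization. Matched by words, they included 8 pectate lyases (3 fell), 7 lytic transglycolases (2 rose) and 4 Bet v I-type sequences (3 rose). These families are also in the cell wall or pathogenesis-related lists, so most of these calls do not mark an organ.

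**Figure D3:**
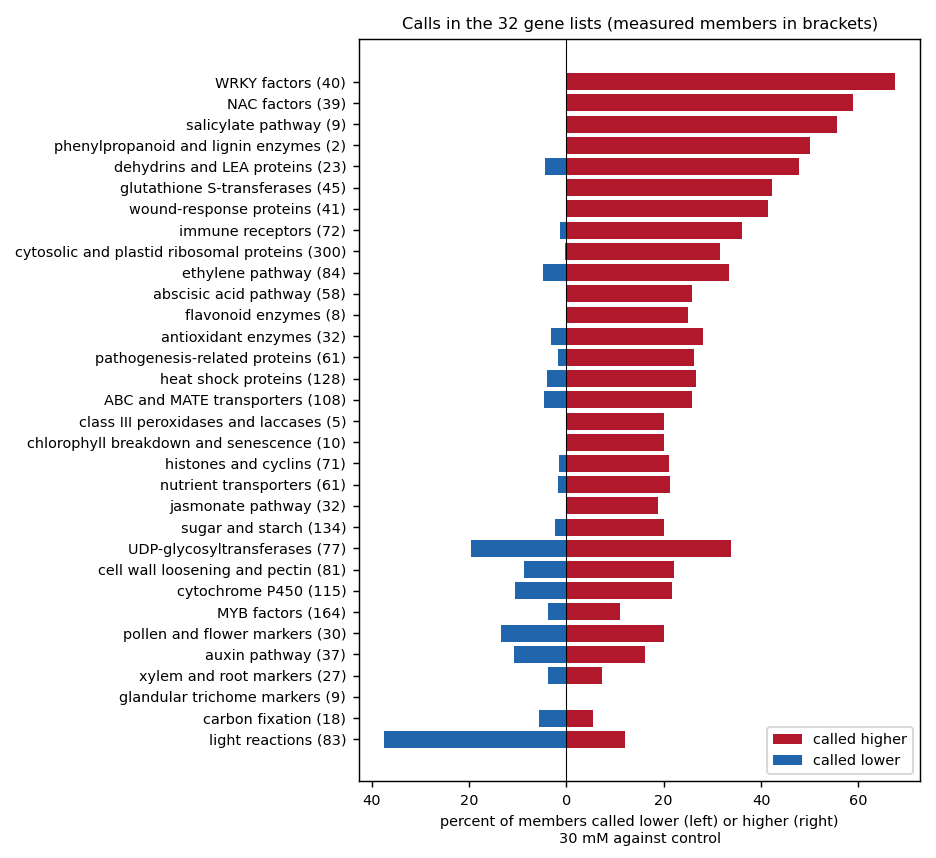
Bars give the percent of measured members of each of 32 gene lists that were called higher or lower at 30 mM against control, with the number of members beside each list. WRKY factors (27 of 40 higher) and NAC factors (23 of 39) have the highest shares among lists of at least 10 members and light reactions the highest share lower (31 of 83), while lists such as MYB factors (18 higher and 6 lower as deposited) turn to 12 and 29 after quantile normalization.

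Both doses were compared with each other to find what the step from 15 to 30 mM added. The aldo/keto reductase T15_3_TRINITY_DN17633_c0_g2 stood at 1.54 ± 0.763 FPKM at 15 mM and 90.6 ± 46.5 at 30 mM (log2 fold change 5.08, SE 0.38, adjusted p = 0.00132). The glutathione S-transferase T15_1_TRINITY_DN13646_c1_g1 rose from 3.77 ± 1.27 to 59.2 ± 21.6 FPKM (log2 fold change 3.61, SE 0.36, adjusted p = 0.0025), and the cytochrome P450 T15_1_TRINITY_DN32985_c0_g1 from 2.44 ± 0.896 to 37.6 ± 10.8 FPKM (log2 fold change 3.49, SE 0.25). The WRKY sequence T15_2_TRINITY_DN31591_c0_g1 rose from 2.59 ± 1.04 to 41.7 ± 6.68 FPKM (log2 fold change 3.60, SE 0.23, adjusted p = 6.7e-04). The fructose-bisphosphate aldolase-type sequence T15_3_TRINITY_DN16383_c0_g1 fell from 50.7 ± 5.3 to 16.3 ± 2.65 FPKM (log2 fold change -1.59, SE 0.16, adjusted p = 0.00281). Falls were also found in the GUN4-like sequence T15_3_TRINITY_DN27255_c0_g1 from 39.5 ± 8.37 to 12.9 ± 2.41 FPKM (log2 fold change -1.54, SE 0.19) and the Thi4 sequence T30_1_TRINITY_DN15030_c0_g1 from 217 ± 82.2 to 52.3 ± 18.5 FPKM (log2 fold change -2.02, SE 0.32, adjusted p = 0.0143). The Thi4 call was lost without 15 mM replicate 1 (adjusted p = 0.0558), 30 mM replicate 1 (0.0575) or 30 mM replicate 3 (0.0524). The groups of these sequences did not overlap, as in every call of this comparison and in 19.5% of all sequences tested. In all, limma called 1371 sequences, 1066 higher and 305 lower, with 7444 under an unadjusted p of 0.05. The split was 1107 to 1129 after quantile normalization, 1246 to 899 after median-of-ratios rescaling and 1787 to 685 with the 4 most abundant sequences left out. The count was 897 without control replicate 1, 518, 820 and 875 without 15 mM replicate 1, 2 or 3, and 607 and 576 without 30 mM replicate 1 or 3.

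Between the doses, 17 of 40 WRKY sequences rose and none fell (22 and 1 adjusted over the list alone; median 0.8; camera adjusted p = 4.6e-08, and adjusted p = 0.9944 with an estimated correlation). Of the other lists in this paragraph the estimated correlation gave an adjusted p = 0.9996. Glutathione S-transferases had 8 rises and no fall among 45 (18 and 0 adjusted over the list alone; camera adjusted p = 0.001, and 0.0508 among sequences with a mean of at least 5 FPKM). NAC factors had 7 rises and no fall among 39 (17 and 3 adjusted over the list alone; camera adjusted p = 0.0176, and 0.0568 without 30 mM replicate 3). Ribosomal proteins had 6 rises among 300 (15 higher and 1 lower adjusted over the list alone; median 0.35; camera adjusted p = 3.5e-04). Light reactions had 13 falls and 4 rises among 83 (39 and 7 adjusted over the list alone; median -0.5; camera adjusted p = 2.4e-13). Carbon fixation was ranked lower (median -0.17; camera adjusted p = 0.0218, and 0.0737 without 30 mM replicate 3) with 0 of 18 called by limma. Auxin sequences were ranked lower with 2 falls and 1 rise among 37 (10 and 5 adjusted over the list alone; camera adjusted p = 4.0e-04), and MYB-type sequences with 4 rises and 4 falls among 164 (8 and 7 adjusted over the list alone; median -0.02; camera adjusted p = 0.00615, and 0.11 against all sequences as background). After quantile normalization the rises and falls were 15 and 1 for WRKY, 10 and 1 for glutathione S-transferase, 7 and 2 for NAC, 9 and 4 for ribosomal protein, 4 and 32 for light-reaction, 0 and 2 for carbon fixation, 1 and 9 for auxin and 3 and 19 for MYB-type sequences. With the 4 most abundant sequences left out, 39 ribosomal protein sequences rose and 1 fell. Of the other 24 lists, limma called the most members among cytochrome P450 (15 higher and 9 lower of 115) and UDP-glycosyltransferase sequences (17 and 5 of 77). Camera called none of these 24 lists against the other annotated sequences. Against all sequences it called 9 of them higher: heat shock (adjusted p = 6.2e-04), pathogenesis-related (0.00227), ethylene (0.00861), wound-response (0.00873), immune receptor (0.0105), dehydrin and LEA (0.0116), salicylate (0.0213), antioxidant and phenylpropanoid sequences (0.0317 each). The estimated correlation, run against annotated sequences, gave each of these an adjusted p = 0.9996.

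Sequences called at both doses against the control were counted to ask whether the doses moved the same transcripts. There were 27 called higher at both doses and 7 called lower at both, and no sequence was called in opposite directions. The WRKY sequence T15_2_TRINITY_DN9367_c0_g1 was among the former, with 2.57 ± 0.614, 11.4 ± 1.9 and 35.6 ± 4.79 FPKM at 0, 15 and 30 mM (log2 fold change 3.37 at 30 mM, SE 0.18, adjusted p = 8.1e-05), as was the NB-ARC sequence T30_2_TRINITY_DN299_c0_g1. Independent lists of these sizes would share 3.7 higher and 0.123 lower sequences, but these lists use the same controls and are not independent. Of the 4425 sequences called higher at 30 mM, 95.6% also had a positive log2 fold change at 15 mM, with medians of 0.96 and 0.36 at the higher and lower dose, and 1039 were also called higher at 30 mM against 15 mM. Of the 775 called lower, 87.7% were negative at 15 mM, with medians of -0.95 and -0.26, and 195 were also called lower at 30 mM against 15 mM. A simulation added after the data were seen took the measured 30 mM means and an unchanged 15 mM group in 50 sets. These sets share the controls and called more sequences at 30 mM (7453 higher and 1907 lower on average), and the same shares were 60.5% and 65.7% on average. In them at most 1 sequence was called in the same direction at both doses. After quantile normalization, which removes the shift of the median at 15 mM, the measured shares were 88.8% and 91.2%. Over all sequences 74.2% had the same sign at both doses, against 66.7% (67.4% at most) in 100 simulated sets with both doses unchanged against the same controls. These sets hold no shift of the median, while the deposited medians were 0.149 at 15 mM and 0.181 at 30 mM. Part of that difference may therefore come from the scale, and the share was not computed after rescaling. The correlation of fold changes across sequences, which are not independent replicates, was 0.509 against 0.5 simulated. It lay below the highest simulated value of 0.516. These sets hold no change at 30 mM, while many sequences were called there in the data. The comparison of correlations therefore cannot tell whether there is an excess. The covariance was 0.112 against 0.0686 simulated (0.0725 at most), a difference of 0.0434. The simulated sets already share the controls, but their noise is independent between sequences. The controls are too few to be divided, so noise common to many sequences in the shared controls may still make part of the excess. The 34 shared calls became 3, 3 and 7 without control replicate 1, 2 or 3. They became 6, 115 and 4 without 15 mM replicate 1, 2 or 3, and 5 and 20 without 30 mM replicate 1 or 3.

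Sequences outside the annotation were examined because the series concerns long non-coding RNAs. At 30 mM against control 1549 of these 30569 sequences rose and 373 fell. T15_1_TRINITY_DN10539_c2_g1 was at 2.17, 0 and 0.88 FPKM in the control libraries, 25.22, 12.29 and 32.7 at 15 mM and 167.22, 102.87 and 94.5 at 30 mM (log2 fold change 6.03 at 30 mM, adjusted p = 2.2e-04). Its call at 15 mM (log2 fold change 3.65, adjusted p = 0.0366) was lost without any library except 15 mM replicate 2 (adjusted p = 0.063 to 0.179). T30_2_TRINITY_DN14566_c0_g1 was listed at 0 in all control and 15 mM libraries and at 25.11, 15.11 and 20.57 FPKM at 30 mM (adjusted p = 4.3e-05). T30_3_TRINITY_DN61803_c0_g1 was at 11.79, 12.74 and 8.88 FPKM in the controls and listed at 0 in all 6 treated libraries (adjusted p = 1.3e-04 at 15 mM and 4.3e-05 at 30 mM), including 30 mM replicate 3, the library whose assembly gave it. At 15 mM 19 of these sequences rose and 7 fell against the control, with 2539 under an unadjusted p of 0.05, and between the doses 410 rose and 148 fell. After quantile normalization the split at 30 mM was 898 higher to 961 lower, at 15 mM 24 to 16 and between the doses 435 to 409. After median-of-ratios rescaling these splits were 982 to 1000, 24 to 17 and 442 to 350, and at 30 mM the split was 1515 to 668 with the 4 most abundant sequences left out. The median of their mean FPKM was 0.78, against 2.3 for annotated sequences, and their coding potential was not tested. The 26 calls at 15 mM became 6, 5 and 10 without control replicate 1, 2 or 3, then 9, 57 and 6 without 15 mM replicate 1, 2 or 3, and 9 without 30 mM replicate 1. The 1922 calls at 30 mM became 855, 908 and 1181 without control replicate 1, 2 or 3 and 1087 without 30 mM replicate 1. The 558 calls between the doses became 238, 356 and 345 without 15 mM replicate 1, 2 or 3 and 262 and 256 without 30 mM replicate 1 or 3.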

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

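The settings with the 4 most abundant sequences left out, with assemblies of the third group and with each sequence tested without its own library were chosen after the data were seen. Camera's background was first all sequences. The annotated background behind the reported list calls was chosen after that first result had been seen. The other settings were chosen before. Counts below follow the order 15 mM against control, 30 mM against control and 30 mM against 15 mM where all are given, and "outside" marks sequences outside the annotation. No direction of a named sequence changed under any setting, and robust moderation moved no count by over 1.5 times. A pseudocount of 0.1 gave 102 calls at 15 mM and 92 shared by both doses; a pseudocount of 5 gave 5 (5 outside) and 2. Without a filter, which adds sequences to the adjustment, calls were 4, 3401 and 746 (4, 1112 and 266 outside), with 2 shared. With a mean of at least 5 FPKM, which leaves fewer sequences, they were 213 and 2380 (51, 536 and 231 outside), with 201 shared. Quantile normalization gave 76 and 2236 calls in the first and last comparison (40 and 844 outside) and 60 shared, median-of-ratios rescaling 71 and 2145 (41 outside at 15 mM) and 56, and leaving out the 4 most abundant sequences 76 and 2472 (925 outside between doses) and 63. Fits of only the 6 libraries compared gave 14 and 403 (14 and 186 outside) and 2 shared. Array weights gave 793 calls at 15 mM (362 outside, 853 outside between doses) and 575 shared. An absolute log2 fold change of at least 1 left 2372 and 876 calls at 30 mM against control and against 15 mM (980 outside against control). Only sequences from assemblies of the third group gave 5, 1250 and 215 (3, 396 and 71 outside), and 26 of the 27 named sequences among them were called. Testing each sequence without its own library gave 11, 3435 and 761 (10, 1209 and 294 outside) and 6 shared. The cause of these shifts was not tested where the setting does not show it.

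With the replicate number as a block the calls were 4, 3642 and 851 (3 and 321 outside in the first and last comparison) and 2 were shared. Residuals of libraries with the same number correlated at -0.013 to 0.027, and 4 of 9 libraries correlated best with their own number, so the numbers were not treated as pairs. Leaving out each library in turn gave 5 to 135 calls at 15 mM (5 to 57 outside), 2350 to 5773 at 30 mM against control (855 to 2112 outside), 518 to 1572 between the doses (238 to 608 outside) and 3 to 115 shared by both doses. The number of list calls was 21 to 31 with 1 library left out, against 26 as reported, and of 88 named calls 72 to 85 were kept. Of the named calls at 30 mM against control 54 of 56 were kept in every such fit, of those between the doses 15 of 20 and of those at 15 mM 1 of 12. The 1 kept at 15 mM was T30_3_TRINITY_DN61803_c0_g1, listed at 0 in every treated library, including the library whose assembly gave it. Of the 26 list calls, 0 were made with an estimated correlation. Camera against all sequences, a background that holds sequences no list could contain, made 41 list calls in all and kept 18 of the 26, so that 8 were lost. The pollen and flower markers at 15 mM turned from lower to higher with a mean of at least 5 FPKM (adjusted p = 0.155, not called), against adjusted p = 0.0176 as reported; the cause was not tested. Over 88 named calls and 26 list calls, 112 of 114 were the same with a pseudocount of 0.1, 102 with 5, 99 without a filter, 106 after quantile normalization, 105 after median-of-ratios rescaling and 113 with array weights. FPKM summed per gene was not run. How far depth limits low values was not tested.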

Other observations

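The tests of Pfam families, of 15 mM assemblies, of rescaled library scores and of regroupings that keep the 30 mM libraries together were chosen only after the data were seen; the other tests were written down before their results. Families of receptor and calcium signalling held many rises at 30 mM against the control. Of 43 sequences with the D-mannose binding lectin domain, found in plant receptor-like kinases, 28 rose and none fell (median log2 fold change 0.83; camera adjusted p = 1.3e-04), and of 36 with the S-locus glycoprotein domain, which often sits in the same kinases, 21 rose and none fell (adjusted p = 0.00313). EF-hand pairs, the calcium-binding units of calmodulin and its relatives, rose in 29 of 61 sequences and fell in 1 (median 0.69; adjusted p = 0.00238). VQ proteins, which bind WRKY factors, rose in 11 of 16 (median 0.97; adjusted p = 0.00132). Peroxidases of Pfam family PF00141 rose in 19 of 28 and fell in 1 (median 1.17; adjusted p = 5.8e-04), although the list named class III peroxidases and laccases held only 5 sequences by its words. With an estimated correlation the adjusted p = 0.9994 for every family in this part. After quantile normalization rises still outnumbered falls, 19 to 1 for the lectins, 16 to 2 for the S-locus domain, 19 to 3 for EF-hands, 8 to 0 for VQ proteins and 17 to 2 for the peroxidases.

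Families of protein turnover and fatty acid elongation also held rises. Of 38 U-box sequences, a class of ubiquitin ligases, 18 rose and none fell (median 0.54; adjusted p = 0.009), with 14 and 3 after quantile normalization. Of 17 proteasome subunits 11 rose and none fell (median 0.78; adjusted p = 0.0183), with 4 rises after quantile normalization. FAE1-type enzymes of very long-chain fatty acid elongation rose in 7 of 10 (median 0.99; adjusted p = 0.0392). In the other direction, 4 of 12 glycosyl hydrolase family 9 sequences, the plant endoglucanases of the cell wall, fell and none rose (median -0.43; adjusted p = 1.6e-06), and 5 fell after quantile normalization. Of 22 NPH3-type sequences, relatives of a phototropism protein, 4 fell and 1 rose (adjusted p = 0.00238), with 7 and 1 after quantile normalization and 6 and 1 after median-of-ratios rescaling.

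Most sequences called at 30 mM against control were higher. A few very abundant sequences may set the FPKM scale: with the 4 most abundant left out, 75.5% of the calls were higher (73.6 to 78.1% with 1 library left out as well), against 85.1% before, which lies between what such a cause would give and what it would forbid, so it cannot be told apart from a true excess. Sequences assembled from 30 mM libraries were not the whole of the excess on the deposited scale. Among sequences from 15 mM assemblies 85.1% of the calls (1236 higher, 217 lower) were higher. The share was 93.9% for 30 mM assemblies (2217 higher, 144 lower) and 70.1% for control assemblies (972 higher, 414 lower). It thus differed with the assembly, so a part of the excess may come from where sequences were assembled. After median-of-ratios rescaling 54.6% of the calls were higher, and after quantile normalization 50.8%. Both rescalings bring the median change of all sequences to -0.01, so they cannot separate an effect of the scale from a true excess. A true excess of rises at 30 mM stays open as well, because FPKM carry no outside standard.

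Sequences were higher in the library whose assembly gave them than in the other libraries of its group, in 9 of 9 libraries. A candidate explanation is that sequences with few reads were assembled where their reads happened to fall. The excess was 1.17 log2 under 1 FPKM, 0.54 at 1 to 5 FPKM and 0.08 at a mean of at least 5 FPKM (-0.32 to 0.38 over libraries), as that explanation predicts. The excess was excluded as the whole cause of the calls at 30 mM, since 3435 sequences were called with each tested without its own library, within the 2350 to 5773 found with 1 library left out. No biological explanation was tested, and 217 sequences were listed at 0 in their own library.

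The 15 mM replicate 2 lay nearer to the controls than the other 15 mM libraries did. On sequences called at 30 mM without the control being scored, its score was 28.2% of the distance from control to 30 mM, against 4.5 to 17.1% for the left-out controls and 41.5 and 45% for the other 15 mM libraries. The tables argue against a control with a wrong label: its score lay above the highest control by 11.1 points as deposited, less than the controls' range of 12.6, but with the 4 most abundant sequences left out it was 32.5% against 5.8 to 16.8% for the controls (15.7 points above, range 11), and the margin also exceeded the range after quantile normalization (18 against 6.4) and median-of-ratios rescaling (16.8 against 9.8). Very abundant sequences may account for much of the gap, which was 15.1% of the distance below the other 15 mM libraries and 6.1% with the 4 most abundant left out. A weaker response of these leaves stays open as well.

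The 6 libraries of each comparison can be split into 3 and 3 in 10 ways, the real one included, too few for a share under 0.05. The real split was the 1 with the most calls in each. The values were 44 calls against at most 15 in another split at 15 mM (26 against 15 outside the annotation), 5200 against 12 at 30 mM (1922 against 12) and 1371 against 15 between the doses (558 against 15). For calls shared by both doses, 2 of 100 drawn regroupings of the 9 libraries gave 34 or more, the real one included; the other gave 799 and was the regrouping in which the 30 mM libraries served as the shared reference, which points to the distance of the 30 mM libraries from the rest. Nearly all regroupings break up the 30 mM libraries, so they do not test the 15 mM grouping. With the 30 mM libraries kept together there are 20 regroupings, too few for a share under 0.05, with 34 shared calls in the real one and at most 10 in another.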
